A study of Mus musculus with 14 samples.

How the data were processed

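The series holds 14 RNA-seq libraries from dorsal skin of wild-type C57BL/6 mice aged 2 or 24 months. Per the labels, epithelial cells were sorted by flow cytometry into Trizol LS, RNA was purified on Direct-zol columns, and libraries were built with a TruSeq mRNA kit. Of these, 12 libraries form 6 groups of 2: bulge stem cells from telogen (resting) skin, interfollicular epidermis from telogen skin, and bulge stem cells from depilated skin, called activated bulge stem cells here, each at both ages. The other 2 libraries come from wounded epidermis, with 1 library per age. The labels do not say whether libraries of one group came from separate animals, so p-values measure only the spread between these libraries. No sex is given.

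Reads were aligned with TopHat and quantified with Cufflinks on the mouse build mm9, per the submitters' processing notes, which give no versions. For the 12 libraries the authors deposited FPKM (fragments per kilobase of transcript, scaled to library size) for the same 28018 annotated transcripts in every library. These values lie 12533 to 18522 times above the usual FPKM scale, a scaling as upper-quartile normalization would give, which was inferred from the values and is not stated in the labels. All 12 libraries were therefore divided by one common constant, 16679.9, which changes no ratio between them. Printed FPKM are on that scale. For the 2 wounded libraries the authors deposited FPKM on about the usual scale, for Ensembl transcripts together with newly assembled ones, 108060 transcripts at 2 months and 109978 at 24 months. Values of these 2 libraries come from another annotation, were not put in one fit with the 12, and were set beside resting epidermis only as values.

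Depth was estimated from the deposited coverage and the width of the confidence bounds. The 12 libraries held 21.7 to 43.3 mega-fragments (M). For the wounded libraries only the covered bases could be had, 2947.5 megabases at 2 months and 3232.8 megabases at 24 months.

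FPKM were summed over the transcripts of each gene symbol, giving 22033 genes, of which 3770 had more than 1 transcript. Genes entered the tests with FPKM of at least 1 in at least 2 of the 12 libraries and a longest transcript of at least 300 nt. Krt5 and Krt14, the keratins of basal keratinocytes, were left out because they were listed at 0 in 7 and 3 of the 12 libraries beside values above 1000 FPKM in others, so the zeros were taken as failed estimates. This left 12468 genes. Values were transformed as log2(FPKM + 1) and fitted with limma 3.58.1 in R 4.3.3, with one mean per group over all 12 libraries, eBayes with trend, two-sided contrasts, and Benjamini-Hochberg adjustment within a comparison, with calls at an adjusted p under 0.05. With 2 libraries per group the spread is shared across the 6 groups, and the median standard error of a difference between groups of 2 was 0.325 on the log2 scale. Where leaving out a library leaves 1 in an arm, that library is assumed to vary like the other groups. On simulated data with the same layout and 200 changed genes, the age comparison in telogen bulge stem cells recovered 11.9% of changes of 1, 59.7% of changes of 2 and 92.4% of changes of 3 on the log2 scale. The mean over the 3 populations recovered 52.2% of changes of 1. The simulation gave every group the same spread per gene and independent noise, unlike the real libraries. Without changes it put 4.75% to 5.41% of genes at an unadjusted p under 0.05 in the age comparisons. The real ones put 0.826% to 2.25% there, so the recovered shares do not give the power of the real tests.

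Before the data were examined, 41 gene lists (31 with at least 5 genes tested), covering programs of follicle, epidermis, growth, stress and immunity and markers of other cell types, were fixed together with the comparisons, thresholds, most alternatives and the rule for naming genes. Lists were tested with camera (limma, preset correlation 0.01), which compares a list with all other genes, beside camera with an estimated correlation and fry, and adjusted over the 31 lists within a comparison. Over 9 comparisons this made 279 list tests. In each comparison the text draws on the 10 rises and 10 falls largest in log2 change among called genes with separate groups, a higher mean of at least 5 FPKM and a proper name, on the 4 members of each list with the smallest p, and, where no gene passed, on up to 5 of the smallest p values. Genes outside that rule are said to be chosen after their values were seen. Some genes that the rule names are not reported here. Alternatives covered normalization, filter, pseudocount, the gene's main transcript, the trend, the libraries fitted, a replicate block and each library left out in turn. Library weights, 2 further forms of the block, equal library totals, leaving out 4 libraries by replicate number, each library left out for the lists, and the annotated transcripts alone in the wounded libraries were added after seeing the data.

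The wounded libraries were compared without a test. Genes were summed over transcripts of at least 300 nt, divided by median-ratio size factors of 0.954 at 2 months and 1.05 at 24 months, and kept with FPKM of at least 5 in either library, leaving 9388 genes. Lists were placed as a percentile among 10000 random lists of equal size matched on expression. The keratins Krt1, Krt5, Krt6a, Krt6b, Krt14, Krt15, Krt16 and Krt17 had no gene entry with a symbol in these 2 libraries and were not analysed here there. Python 3.11.15 with pandas 2.3.3 and numpy 2.4.6 was used for these steps, and matplotlib 3.10.9 for the figures.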

Results

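The series set epithelial keratinocytes of young mice beside those of aged mice. RNA was measured in bulge stem cells of the hair follicle in resting (telogen) skin, in interfollicular epidermis of resting skin and in bulge stem cells of depilated skin, with 2 libraries for each population at 2 and at 24 months, and in wounded epidermis with 1 library per age. The estimated depth, in mega-fragments (M), was 34.8, 35.2, 35.9 and 43.3 M in telogen bulge stem cells, 37.8, 21.7, 39.6 and 32.7 M in epidermis, and 33.1, 31.2, 32.1 and 22.8 M in activated bulge stem cells, each in the order replicates 1 and 2 at 2 months, then at 24 months. The first 2 principal components held 47.1% and 28.8% of the variance. Libraries of one group were closest in telogen bulge stem cells, with a correlation across genes (which are not independent replicates) of 0.984 at 2 months and 0.997 at 24 months, against 0.943 and 0.948 in epidermis and 0.919 and 0.959 in activated cells.

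The sorted populations differed in their sex-linked transcripts. Xist, the RNA that silences an X chromosome in female cells, was at 0.0398 ± 0.00158 FPKM (SD, n = 2) in telogen bulge stem cells at 2 months but at 60.1 ± 62.7 in activated bulge stem cells at 2 months and 82.1 ± 83 at 24 months, with 15.8, 104.5, 23.4 and 140.8 FPKM in the 4 activated libraries. The Y-linked translation factor Eif2s3y was at 31.1 FPKM in telogen bulge stem cells and 30 in epidermis at 2 months, and at 0.0505 in activated cells. The activated libraries thus held Xist and almost no Y-linked RNA, and the other 8 libraries the reverse, so every difference between resting and activated cells coincides with this split.

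**Figure D1:**
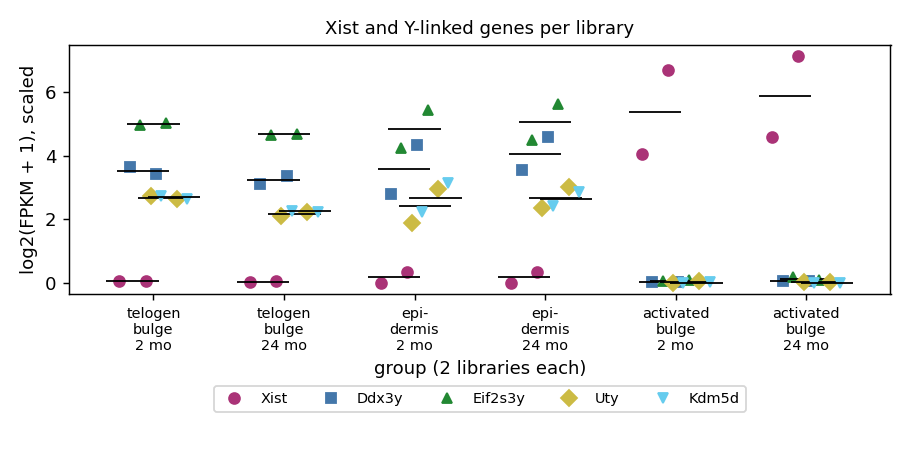
log2(FPKM + 1) of Xist and 4 Y-linked genes in each of the 12 libraries by group, with a point per library and a line at each group mean. Xist lies between 15.8 and 140.8 FPKM in the 4 activated bulge stem cell libraries and below 1 in the other 8.

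Telogen bulge stem cells were first set against epidermis at 2 months, for the difference between follicle and epidermis. Cd34, a surface marker of bulge cells, was at 1188 ± 163 FPKM in bulge stem cells and 4.12 ± 2.31 in epidermis (SD, n = 2), a log2 difference of 7.93 (SE 0.469, limma adjusted p = 3.5e-06), and lies on chromosome 1 at 196765015 to 196787486 in mm9. Krt24, a keratin of the bulge on chromosome 11 at 99141407 to 99146552, was higher by log2 6.76 (SE 0.330, adjusted p = 1.05e-06), at 575 against 4.31 FPKM. Of the 25 bulge stem cell markers on the list, 24 were higher (25 adjusted over the list alone), among them the transcription factor Tbx1 by log2 6.13, the matrix protein Ltbp2 by 5.89, Lgr5, a receptor of cycling stem cells, by 5.46 and Nfatc1, a regulator of bulge quiescence, by 2.33. Their median was 3.64 (camera adjusted p = 4.47e-20, and adjusted p = 0.0196 with an estimated correlation). Genes of BMP signalling and quiescence were higher as well, 12 higher and 1 lower of 16 (13 and 1 adjusted over the list alone), with Id2 by log2 4.81 and the BMP antagonist Nog by 4.33 (camera adjusted p = 1.13e-06, and adjusted p = 0.0196 with an estimated correlation).

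Cell cycle genes were lower in the resting bulge, 34 of 38 (35 adjusted over the list alone), with a median of -2.37 (camera adjusted p = 6.49e-27, but adjusted p = 0.0676 with an estimated correlation). Mki67, a marker of dividing cells, was at 2.27 FPKM in the bulge and 31.6 in epidermis. Immediate early and stress genes were lower for 13 and higher for 1 of 25 (15 and 1 adjusted over the list alone), with the transcription factor Klf2 lower by log2 -3.08, and JAK-STAT genes were lower for 7 and higher for 1 of 22 (7 and 1 adjusted over the list alone). Their adjusted p = 0.759 and 0.509 with an estimated correlation. The same test gave lower medians for interferon response (-0.83, 0 higher and 2 lower of 17), keratinocyte wound response (-0.99, 3 and 6 of 31), cytokines (-0.71, 1 and 3 of 21, including Il33 by -3.70), p53 targets (-0.55, 1 and 7 of 18), MHC class I presentation (-1.12, 0 and 3 of 13) and inhibitors of cyclin-dependent kinases with senescence genes (-1.24, 3 and 6 of 15), and a higher median for the Hedgehog pathway (0.85, 5 and 1 of 12, with its target Gli1 by 3.67). For these lists, adjusted p = 0.509 to 0.772 with an estimated correlation. Adjusted over the list alone, 0 and 1 interferon genes, 2 and 8 p53 targets, 0 and 4 MHC class I genes, 3 and 8 senescence genes and 7 and 1 Hedgehog genes passed, and the wound response and cytokine counts did not differ. Without replicate 1 of epidermis at 2 months the camera calls of wound response (-0.40), MHC class I (-0.59), senescence (-0.94) and Hedgehog genes (0.70) were lost. The interferon response median was then -0.41. The Hedgehog call was also lost without replicate 1 of the telogen bulge at 2 months (0.64). The wound response median was -1.69 without its replicate 2 and -1.61 without replicate 2 of epidermis.

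Over all genes, 1620 were higher and 892 lower in bulge stem cells, 2512 of 12468. Besides Cd34 and Krt24, the largest rises were Ctgf (7.36), Wfdc3 (7.28), Angptl7 (6.66), Tgm5 (6.64), Shisa2 (6.53), Col8a2 (6.48), Grem1 (6.35) and the calcium-binding S100a4 (6.35). The largest falls were Ly6c1 (-4.46), Ly6a (-4.39), the AP-1 subunit Fosl1 (-4.35), the EGF receptor ligand Epgn (-4.29), Ppp2r2c (-4.18), Il20ra (-4.10), the stromelysin Mmp3 (-3.90), Adamts14 (-3.85), Ly6c2 (-3.77) and Cpxm2 (-3.75). The count was 1289 without replicate 1 and 1433 without replicate 2 of the telogen bulge libraries at 2 months. Quantile normalization gave 1417 higher and 1310 lower, and equal library totals 1163 higher and 1065 lower.

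Activation was then read as the difference between bulge stem cells of depilated and of resting skin at 2 months. Of 38 cell cycle genes, 37 rose (38 adjusted over the list alone) with a median of 2.85, and Mki67 went from 2.27 ± 1.62 to 57.7 ± 34.4 FPKM (SD, n = 2, log2 change 4.13, SE 0.666, limma adjusted p = 0.00356) and Top2a, a topoisomerase of dividing cells, from 6.03 to 99 FPKM. Cd34 fell from 1188 to 74.4 ± 21.8 FPKM (SE of the log2 change 0.469, adjusted p = 0.000668), and Krt24 fell by 4.49 (SE 0.330, adjusted p = 0.000153). Krt15, a further bulge keratin, fell by 2.52 (adjusted p = 0.0155), while Nfatc1 was at 54.8 and 65.2 FPKM (adjusted p = 0.742).

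The cell cycle list had camera adjusted p = 6.2e-34 and fry adjusted p = 0.000116, but adjusted p = 0.117 with an estimated correlation. BMP and quiescence genes fell for 5 of 16 (6 adjusted over the list alone), among them Nog by -2.96, Id2 by -2.86 and the cell cycle inhibitor Cdkn1c by -2.27, with camera adjusted p = 0.00308 and adjusted p = 0.15 with an estimated correlation. Immediate early genes rose for 8 of 25 (13 higher and 1 lower adjusted over the list alone), with the transcription factors Egr3 by 4.12 and Nr4a1 by 3.96. JAK-STAT genes rose for 6 of 22 (7 adjusted over the list alone), among them Bcl3 by 2.79, the feedback inhibitors Socs3 and Cish by 2.29 each, and Myc by 1.44. Wound response genes rose for 6 and fell for 1 of 31 (6 and 1 adjusted over the list alone), with Epgn by 3.66 and the cytokine Il24 by 3.26, and Flrt2 by -1.17. Cholesterol synthesis genes rose for 3 of 17. Ribosomal proteins had a median of -0.92 with 0 of 49 called, oxidative phosphorylation genes a median of -0.52 with 2 of 70 lower (0 adjusted over the list alone), and the T cell list a median of 0.55 with 1 of 8 higher. Counts for cholesterol synthesis, T cell and sex-linked genes (1 higher and 4 lower of 5) did not differ when adjusted over the list alone. These 7 lists and the sex-linked list were called by camera (adjusted p = 1.86e-06 to 0.0338). Each had adjusted p = 0.893 with an estimated correlation. The calls of wound response (0.15) and cholesterol synthesis genes (0.42) were lost without replicate 1 of the activated cells at 2 months, where the median was 0.95 each for JAK-STAT and T cell genes and -0.99 for oxidative phosphorylation. Without replicate 2, which differed from replicate 1 with transcript length (Spearman 0.60), the calls of oxidative phosphorylation (-0.03) and T cell genes (0.23) were lost. The median was then -0.44 for ribosomal proteins, 0.37 for JAK-STAT and 2.10 for wound response. Without replicate 1 of the telogen bulge at 2 months the calls of cholesterol synthesis (0.74) and T cell genes (0.46) were lost.

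Over all genes 823 rose and 772 fell, 1595 of 12468. Among the largest rises were Xist (5.34), Fosl1 (5.32), Nr4a3 (4.43), Mki67 (4.13), Egr3 (4.12), Adamts1 (4.11), Pla2g7 (4.09), Nr4a1 (3.96) and Top2a (3.93). The largest falls were Angptl7 (-5.11), Eif2s3y (-4.93), Sncg (-4.87), S100a4 (-4.70), Cck (-4.52), Krt24 (-4.49), Wfdc3 (-4.19), Myoc (-4.16), Fgf18 (-4.06), a growth factor of the resting bulge, and Cd34. Of 394 X-linked genes tested, 10.7% were called, against 12.8% of autosomal genes (Fisher's exact two-sided p = 0.22). All 4 Y-linked genes tested were called. Since Xist silences an X chromosome, the X-linked share cannot tell whether the Xist and Y-linked split drives the other calls. The count was 412 without replicate 2 and 546 without replicate 1 of the telogen bulge at 2 months, 1034 and 1031 without replicates 1 and 2 of the telogen bulge at 24 months, and 834 without replicate 2 of the activated cells at 2 months. Quantile normalization gave 1096 rises and 1586 falls, and equal library totals 1375 rises and 537 falls with the median gene shifted by 0.32.

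At 24 months activation gave a profile like that at 2 months in its leading genes. Mki67 went from 1.17 to 49.4 FPKM (log2 change 4.53, SE 0.666, limma adjusted p = 0.0027), and 36 of 38 cell cycle genes rose (38 adjusted over the list alone) with a median of 2.92. Cd34 fell by 3.50 (SE 0.469, adjusted p = 0.00158), from 979 ± 49 to 85.9 ± 8.5 FPKM (SD, n = 2). BMP and quiescence genes fell for 5 of 16 (6 adjusted over the list alone), with Cdkn1c by -3.20, Id2 by -2.90 and Nog by -2.64.

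The cell cycle and BMP lists were called by camera (adjusted p = 1.07e-37 and 0.000945), and each had adjusted p = 0.0885 with an estimated correlation. JAK-STAT genes rose for 4 of 22 (6 adjusted over the list alone), including Socs2 by 2.12, wound response genes for 3 of 31 (3 higher and 1 lower adjusted over the list alone), immediate early genes for 2 of 25, including Egr3 by 2.60, and antimicrobial genes for 1 of 14, the beta-defensin Defb3 by 1.67 (the immediate early and antimicrobial counts did not differ adjusted over the list alone). Ribosomal proteins and oxidative phosphorylation had medians of -0.88 and -0.49 with no gene called, and the sex-linked list had 1 higher and 4 lower of 5. These 7 lists were called by camera (adjusted p = 6.87e-05 to 0.0457), and each had adjusted p = 0.946 with an estimated correlation. Without replicate 1 of the activated cells at 24 months the calls of immediate early (-0.26), antimicrobial (0.12) and sex-linked genes were lost. The medians were then 0.22 for JAK-STAT, 0.52 for wound response and -0.90 for oxidative phosphorylation. Without replicate 2, which also differed with transcript length (Spearman 0.51), the call of oxidative phosphorylation was lost (-0.08). The medians were then -0.48 for ribosomal proteins, 1.69 for immediate early and 2.01 for antimicrobial genes. The immediate early median was 0.34 without replicate 1 of the telogen bulge at 24 months, where its call was lost, and 0.65 without replicate 2. The antimicrobial call was lost without either epidermis library at 2 months.

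Over all genes 512 rose and 486 fell, 998 of 12468. Beside Xist (5.84) and Mki67, the largest rises included Pla2g7 (4.23), Top2a (4.17), Fosl1 (3.99), Akr1c18 (3.83), Ifi202b (3.71) and the mitotic genes Ckap2 (3.68) and Ccnb2 (3.62). The largest falls were Angptl7 (-4.72), Eif2s3y (-4.54), Sncg (-3.90), S100a4 (-3.61), Cd34, the Wnt receptor Fzd9 (-3.47), Calr3 (-3.40), Rab17 (-3.34), Col8a2 (-3.33) and Ppp1r3c (-3.33). The count was 278 and 292 without replicates 1 and 2 of the telogen bulge at 24 months, 654 and 650 without those at 2 months, and 539 and 494 without replicates 1 and 2 of the activated cells at 24 months. Quantile normalization gave 716 rises and 1035 falls, and equal library totals 908 rises and 294 falls with the median gene shifted by 0.36.

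**Figure D2:**
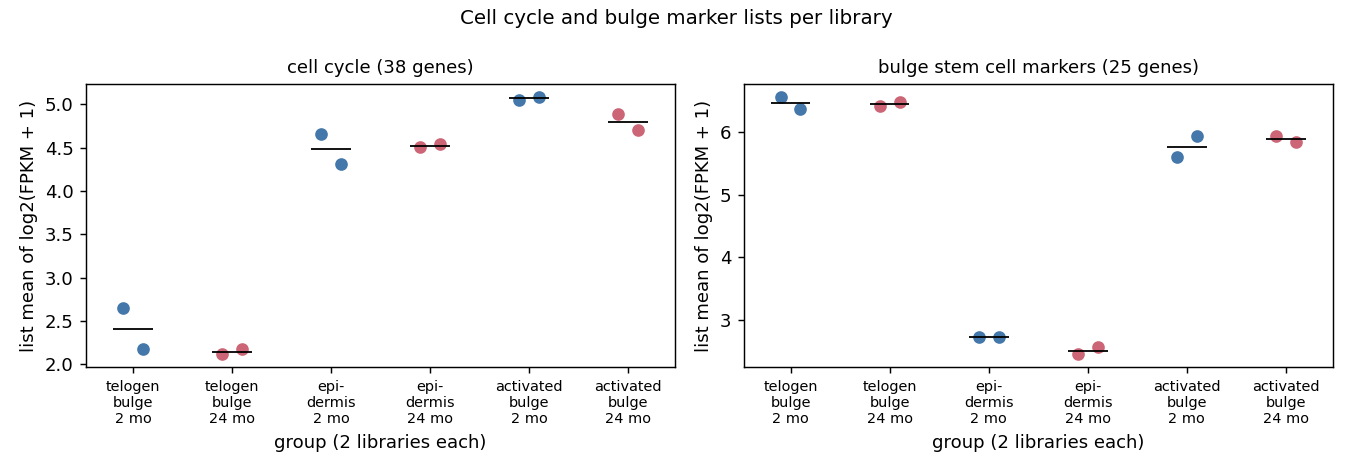
Mean log2(FPKM + 1) of the cell cycle list and of the bulge stem cell marker list in each of the 12 libraries by group, with a point per library and a line at each group mean. Cell cycle genes lie higher in the activated than in the telogen bulge at both ages, by medians of 2.85 and 2.92, and bulge markers lie lowest in epidermis.

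The response to depilation was compared between ages. Between the sets called at 2 and at 24 months, 453 rises were shared where independent lists of those sizes would share 33.8, and 406 falls where they would share 30.1, with 0 genes called in opposite directions. Across genes, which are not independent replicates, the log2 changes had a Pearson correlation of 0.915, a Spearman correlation of 0.902 and a slope of 0.868 at 24 months on 2 months. These comparisons share no library, but both coincide with the Xist and Y-linked split. Both also come from one fit, with one spread per gene over all 12 libraries. The 2 sets of calls are thus not independent, and the 33.8 and 30.1 do not allow for that. Immediate early genes were less high after activation at 24 months, with a median difference of -1.01 and 1 of 25 positive (camera adjusted p = 1.49e-11), as were cholesterol synthesis genes (-0.42, adjusted p = 0.00934), while interferon response genes were higher (0.29, adjusted p = 0.00705). None of these 3 lists held a called gene, and each had adjusted p = 0.969 with an estimated correlation. All 3 depend on single libraries. Without replicate 2 of activated cells at 24 months the calls of immediate early (-0.19, camera adjusted p = 0.09) and cholesterol synthesis genes (0.03) were lost and the interferon response difference was 0.58. Without replicate 1 the interferon call was lost (0.08), the immediate early difference became larger and that of cholesterol synthesis was -0.77. Without replicates 1 and 2 of activated cells at 2 months interferon response was 0.49 and 0.18 and cholesterol synthesis 0.07, with its call lost, and -0.83. Without those of the telogen bulge at 2 months interferon response was 0.45 and 0.18. The cholesterol call was lost as well without replicate 1 of the telogen bulge at 2 months (-0.24) or replicate 2 at 24 months (-0.30).

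For single genes, limma called 0 of 12468 for a difference of activation between ages, with 98 at an unadjusted p under 0.05. The median standard error of this difference was 0.459. On the simulated data it recovered 0% of changes of 1 and 38.8% of changes of 2 on the log2 scale. The 0 calls thus do not show an equal response at both ages. The smallest p values belonged to Emid1 (1.18), Pcp4 (-1.20), Pvr (-1.28), Mtmr7 (-1.42) and Scarf2 (-1.09), each with adjusted p = 1. Leaving out either epidermis library at 24 months, or replicate 2 of the activated cells at 2 months, gave 1 gene.

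Age was compared first in telogen bulge stem cells. The bulge stem cell markers had a median of 0.01 with 14 of 25 positive (camera adjusted p = 0.821). Cd34 was at 1188 ± 163 FPKM at 2 months and 979 ± 49 at 24 months, Krt24 at 575 and 720, and Krt15 at 14846 and 14322 (SD, n = 2), while Fgf18 was at 25.5 and 10.1, Npnt at 50.3 and 22.9 and Fst at 123 and 72.6 FPKM, each with limma adjusted p = 1. No gene passed the test: limma called 0 of 12468, with 182 (1.46%) at an unadjusted p under 0.05, where the simulation without changes gave 5.21%. The test shares its spread with epidermis and activated cells, whose libraries varied more. The median SD within a group was 0.110 and 0.0642 in telogen bulge but 0.297 to 0.383 in the others. The test is thus strict for this population, and 0 calls do not show that age made no difference. The smallest p values were those of Emid1, at 3.23 and 0.678 FPKM (log2 -1.33, SE 0.187, adjusted p = 0.399), the collagen-processing cofactor Pcolce2, at 12.6 and 3.11 FPKM (-1.73, adjusted p = 0.407), the thymus-type protease Prss16, at 1.23 and 5.12 FPKM (1.45, adjusted p = 0.407), Myoc, at 125 and 22.6 FPKM (-2.33, adjusted p = 1) and Nptx1 (-1.11).

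Camera called 5 lists in telogen bulge stem cells, all with 0 single genes called and 0 adjusted over the list alone. MHC class I presentation genes, which carry peptides to the cell surface, were positive for 13 of 13 with a median of 0.47 (camera adjusted p = 0.000114), as in H2-K1 at 410 ± 65.2 and 675 ± 2.21 FPKM and the immunoproteasome subunit Psmb8 at 23.9 and 42.1. The T cell list was positive for 8 of 8 (0.25, adjusted p = 0.0454) and epidermal differentiation for 25 of 29 (0.52, adjusted p = 0.00798), and the latter was -0.29 without replicate 1 at 2 months. Cell cycle genes were positive for 4 of 38 (-0.27, adjusted p = 1.23e-05) and sebaceous gland genes for 5 of 14 (-0.38, adjusted p = 0.0201). Each of the 5 had adjusted p = 0.981 with an estimated correlation. Without replicate 1 at 2 months the cell cycle median was 0.01 (camera adjusted p = 0.652), against -0.51 without replicate 2, so this list rests on that library. The MHC class I median was 0.24 without replicate 1, and the differentiation median 1.17 without replicate 2 at 2 months. The T cell call was lost when any of 6 single libraries was left out, namely each epidermis library, replicate 1 at 2 months (0.17) and replicate 1 at 24 months (0.09), and the sebaceous call without that library (-0.33) or without replicate 2 at 2 months (-0.44). Leaving out either epidermis library at 24 months gave 1 gene called with age in the telogen bulge, and library weights, added after seeing the data, gave 222, the largest of the 27 settings tried.

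In interfollicular epidermis the caspase of inflammasomes, Casp1, was at 5.03 ± 0.87 FPKM at 2 months and 26.1 ± 10.1 at 24 months (SD, n = 2, log2 2.12, SE 0.308, limma adjusted p = 0.256). Atp6v1g3, a proton pump subunit, was at 0.649 and 3.79 FPKM (1.54, SE 0.192, adjusted p = 0.134), and the hormone subunit gene Gpha2 at 31 and 199 FPKM (2.53, adjusted p = 0.897). Limma called 0 of 12468 genes, with 103 at an unadjusted p under 0.05, and Cadps2 (1.13) and Amhr2 (1.52) complete the 5 smallest p values. Leaving out replicate 2 at 24 months gave 1 gene.

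Camera called 8 lists for age in epidermis, with 0 single genes called and 0 adjusted over the list alone. Positive medians were found for ribosomal proteins (0.40, 48 of 49 positive, adjusted p = 3.11e-07), the T cell list (0.23, 8 of 8), oxidative phosphorylation (0.22, 67 of 70), MHC class I presentation (0.29, 13 of 13) and immediate early genes (0.33, 23 of 25). Negative medians were found for bulge stem cell markers (-0.22, 6 of 25 positive, adjusted p = 3.11e-07), sebaceous gland genes (-0.16, 4 of 14) and Wnt targets (-0.11, 6 of 16). For the bulge markers adjusted p = 0.369, and for the other 7 lists adjusted p = 0.939, with an estimated correlation. Each of the 8 depends on single epidermis libraries. Without replicate 2 at 2 months the medians turned to -0.16 for ribosomal proteins, -0.30 for oxidative phosphorylation and -0.20 for MHC class I. The calls of bulge marker (-0.18), sebaceous (-0.50), Wnt (-0.21) and T cell genes (0.38) were lost. Without replicate 1 at 2 months the test of the immediate early list turned (0.26), and the calls of sebaceous (-0.04), Wnt (-0.02) and T cell genes (0.40) were lost. The medians were then 0.97 for ribosomal proteins, 0.79 for oxidative phosphorylation and 0.81 for MHC class I. Without replicate 1 at 24 months the calls of bulge marker (-0.17), MHC class I (-0.04), immediate early (0.26), oxidative phosphorylation (0.13) and ribosomal genes (0.28) were lost. The medians were then -0.49 for sebaceous, -0.36 for Wnt and 0.38 for T cell genes. Without replicate 2 at 24 months the Wnt median turned to 0.01, and the calls of sebaceous (-0.10), immediate early (0.43), oxidative phosphorylation (0.38) and T cell genes (0.25) were lost. The MHC class I median was then 0.69.

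In activated bulge stem cells Krt24 was at 24.6 ± 1.19 FPKM at 2 months and 80.7 ± 2.5 at 24 months (SD, n = 2, log2 1.68, limma adjusted p = 0.558), the only bulge marker to pass when adjusted over the list alone. Immediate early genes were lower at 24 months (median -0.81, 1 of 25 positive, camera adjusted p = 2.42e-10), as were sebaceous gland genes (-0.77, 2 of 14, 8.78e-07), cell cycle genes (-0.27, 1 of 38), endoplasmic reticulum stress genes (-0.29, 0 of 15), Hedgehog genes (-0.21, 2 of 12) and p53 targets (-0.18, 4 of 18). MHC class I genes were higher (0.42, 13 of 13, 1.1e-05), as were interferon response genes (0.25, 15 of 17), bulge markers (0.14, 17 of 25) and ribosomal proteins (0.11, 47 of 49). Each had adjusted p = 0.791 to 0.862 with an estimated correlation. Each of the 10 depends on single libraries. Without replicate 2 at 24 months the calls of immediate early (-0.04, camera adjusted p = 0.8), endoplasmic reticulum stress (0.09), p53 (0.04) and bulge marker genes (0.23) were lost. The medians were then -0.33 for sebaceous, -0.41 for Hedgehog, 0.84 for MHC class I, 0.49 for interferon response and 0.51 for ribosomal genes. Without replicate 1 at 24 months the interferon call was lost with a median near 0. The medians of Hedgehog (-0.09), ribosomal (-0.27) and bulge marker genes (-0.06) or their tests turned, and those of immediate early (-1.80), endoplasmic reticulum stress (-0.72), p53 (-0.37) and MHC class I genes (0.19) moved. Without replicate 1 at 2 months the calls of sebaceous (median near 0, camera adjusted p = 0.654), p53 (-0.04) and endoplasmic reticulum stress genes (-0.14) were lost. The bulge marker median was then -0.06, and those of Hedgehog, MHC class I and ribosomal genes were -0.82, 0.76 and 0.56. Without replicate 2 at 2 months the calls of cell cycle (-0.32) and MHC class I genes (0.22) were lost. The Hedgehog and ribosomal medians turned to 0.22 and -0.32, and those of sebaceous, endoplasmic reticulum stress, p53 and bulge marker genes were -1.40, -0.53, -0.27 and 0.31. The calls of Hedgehog and p53 genes were also lost when any 1 of the 4 epidermis libraries was left out, and that of ribosomal genes without either telogen bulge library at 2 months or either epidermis library at 24 months.

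Markers of other cells moved with these lists. The fibroblast list had a median of -1.22 and the macrophage list -0.51 (camera adjusted p = 0.00193 and 0.032, and adjusted p = 0.791 and 0.851 with an estimated correlation), and replicate 1 at 2 months held the collagens Col1a1 and Col3a1 at 101.5 and 110.6 FPKM, against 3.5 and 0 in replicate 2. Fn1, a matrix protein on the wound response list, was the only member of that list to pass adjusted over the list alone (log2 -1.76, adjusted p = 0.417 over all genes), and the list's median of -0.03 had camera adjusted p = 0.0429 and adjusted p = 0.851 with an estimated correlation. Without replicate 1 at 2 months the medians turned to 0.21 for fibroblast, 0.58 for macrophage and 0.57 for wound response genes, against -2.17, -1.42 and -1.20 without replicate 2. Without replicate 2 at 24 months they were -0.40 for fibroblast, 0.07 for macrophage and 0.13 for wound response genes. Without replicate 1 at 24 months they were -0.84 for macrophage and -0.55 for wound response. The wound response call was lost in both cases, and the macrophage call in the former and without either epidermis library at 2 months.

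Limma called 0 of 12468 genes for age in activated bulge stem cells, with 233 at an unadjusted p under 0.05. The smallest p values were those of Mtmr7, at 6.64 and 1.35 FPKM (-1.72), Prkar2b, a regulatory subunit of protein kinase A (-1.34), Basp1 (-1.29), the glutamate receptor subunit Grik1 (1.43) and Pcp4 (-1.19), each with adjusted p = 0.384. Without replicate 2 at 2 months 6 genes passed.

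The mean age difference over the 3 populations was taken to find changes common to them. MHC class I genes were higher at 24 months, 13 of 13 positive with a median of 0.37, and B2m, their common subunit, was at 908 and 1254 FPKM in telogen bulge, 2035 and 2573 in epidermis and 739 and 1032 in activated cells. Sebaceous gland genes, many of them enzymes of lipid synthesis, were lower, with a median of -0.52 and 3 of 14 positive. Elovl5, which lengthens fatty acids, passed adjusted over the list alone (log2 -0.55, adjusted p = 0.774 over all genes). Cell cycle genes were lower (-0.16, 2 of 38 positive), and ribosomal proteins higher (0.20, 49 of 49 positive). Camera adjusted p was 3.31e-09, 1.62e-08, 2.28e-08 and 9.26e-06 for these 4 lists. They had adjusted p = 0.723 to 0.851 with an estimated correlation. Leaving out 1 library kept the first 3 calls. However, the MHC class I median was 0.23 without replicate 2 of epidermis at 2 months, the sebaceous median -0.26 without replicate 1 of activated cells at 2 months. The cell cycle median was -0.09 and -0.26 without replicates 1 and 2 of the telogen bulge at 2 months and -0.28 without replicate 2 of epidermis at 2 months. The ribosomal call was lost without replicate 2 of epidermis (0.02) or of activated cells (0.05) at 2 months. Its median was 0.40 and 0.37 without the replicates 1 of these groups, and 0.07 and 0.34 without replicates 1 and 2 of activated cells at 24 months.

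A further 8 lists were called for the mean age difference. Medians were positive for T cell (0.23), epidermal differentiation (0.25), MHC class II with Langerhans cell (0.22) and oxidative phosphorylation genes (0.09). They were negative for fibroblast (-0.40), hemidesmosome and basement membrane (-0.07, with the collagen Col4a1 at -0.84 passing adjusted over the list alone), Wnt (-0.06) and Hedgehog genes (-0.07). Camera adjusted p ran from 0.00079 to 0.04, and adjusted p = 0.754 to 0.851 with an estimated correlation. Each of these 8 calls was lost or turned without 3 or more of the 12 libraries, left out in turn, so none is stable. The median was -0.13 for epidermal differentiation, 0.09 for Hedgehog and -0.03 for MHC class II genes without replicate 2 of activated cells at 2 months, and for oxidative phosphorylation -0.06 without that library and -0.09 without replicate 2 of epidermis at 2 months. Without replicate 1 of activated cells at 2 months the fibroblast median was 0.01 and the T cell median 0.14, and without replicate 2 of epidermis at 24 months the hemidesmosome median was -0.01 and the Wnt median 0.06.

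For single genes limma called 0 of 12468 for the mean age difference, with 281 at an unadjusted p under 0.05. With a replicate block within each population, added after the data were seen, 24 genes passed. Without that block, the smallest p values were those of Lhfpl1 (-1.40, SE 0.188, adjusted p = 0.269), at 3.64 and 0.701 FPKM in telogen bulge, 3.24 and 0.38 in epidermis and 5.92 and 2.17 in activated cells, then Casp1 (1.10), Prss16 (0.868) and Basp1 (-0.769), each with adjusted p = 0.323, and Pcolce2 (-0.953, adjusted p = 0.358). Across the 6 pairs of libraries with the same number, 373 of 12468 genes were higher at 24 months in all 6 and 201 lower in all 6. Chance gives 1.5625% each way if the pairs are independent. That was not shown, and the numbers did not link the telogen bulge libraries, so no excess is read from these counts. Without replicate 2 of epidermis at 24 months 1 gene passed, and without replicate 2 of activated cells at 2 months 2 genes.

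**Figure D3:**
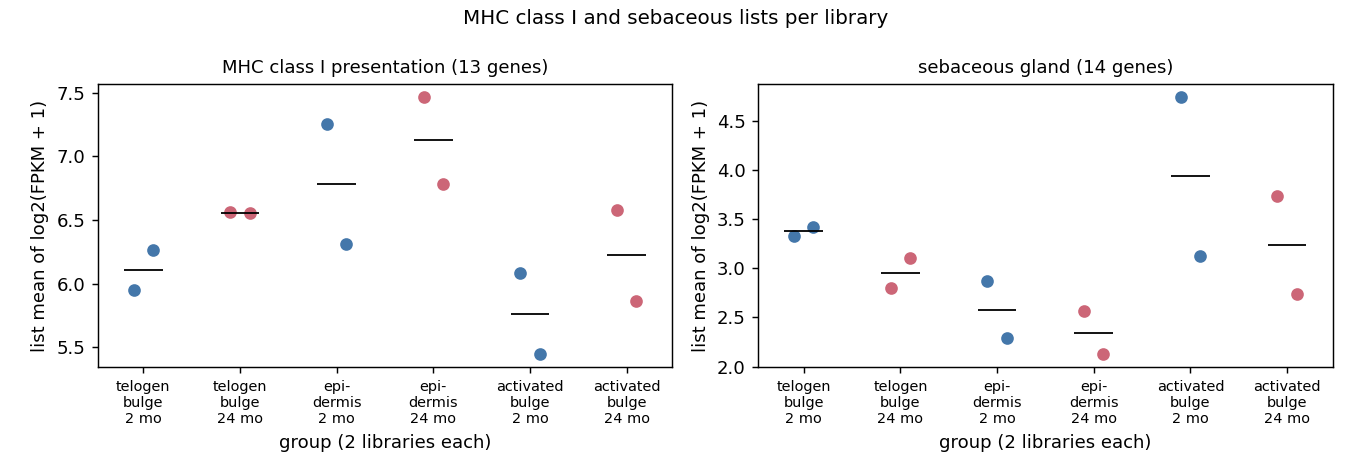
Mean log2(FPKM + 1) of the MHC class I presentation list and of the sebaceous gland list in each of the 12 libraries by group, with a point per library (blue 2 months, red 24 months) and a line at each group mean. The medians over the 3 populations differ by 0.37 and -0.52 between 24 and 2 months, and the 2 libraries of one group lie as far apart as 6.32 and 7.26 for MHC class I in epidermis at 2 months.

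The age difference was finally compared between the telogen bulge and epidermis. Bulge markers differed by a median of 0.31, with 18 of 25 positive, and cell cycle genes by -0.33, with 4 of 38 positive (camera adjusted p = 0.00386 each, and adjusted p = 0.994 with an estimated correlation). The bulge marker call was lost without replicate 2 of the telogen bulge (0.20) or of epidermis (0.38) at 2 months or replicate 1 of epidermis at 24 months (0.23). The cell cycle call was lost without replicate 1 of the telogen bulge (-0.05) or replicate 2 of epidermis (0.04) at 2 months or replicate 2 of epidermis at 24 months (-0.28). Its median was -0.58 without replicate 2 of the telogen bulge or replicate 1 of epidermis at 2 months. Limma called 0 of 12468 genes, with 84 at an unadjusted p under 0.05. The median standard error was 0.459 here, so 0 calls do not show equal age differences. The smallest p values were those of Atp6v1g3 (-1.46), Emid1 (-1.37), Casp1 (-1.73), Pcolce2 (-1.75) and Cadps2 (-0.977), each with adjusted p = 1.

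Wounded epidermis was compared between ages with 1 library each and no test. All 10 Skint genes above the filter were lower in the aged library, with a median log2 ratio of -1.56. Skint1, which shapes the gamma-delta T cells of mouse epidermis and lies on chromosome 4 at 111678874 to 111702143, was at 158 FPKM at 2 months and 49.5 at 24 months. The median lay at percentile 0 of random lists, whose central range without the outer 2.5% on each side was -0.40 to 0.59, and was -1.44 with 10 of 10 lower in FPKM as deposited, where the median of all genes was 0.13. Skint8 was listed at 0 at 2 months and at 2.74 FPKM at 24 months. In resting epidermis Skint1 was at 46.9 and 47.3 FPKM, on another annotation and scale, so these values cannot be read against the wounded ones. On a scale taken over both, a comparison chosen after the data were seen, Skint genes lay higher in wounded epidermis at both ages. Their medians were 2.39 at 2 months (10 of 11 higher) and 0.82 at 24 months (9 of 11), across the Xist and Y-linked split.

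**Figure D4:**
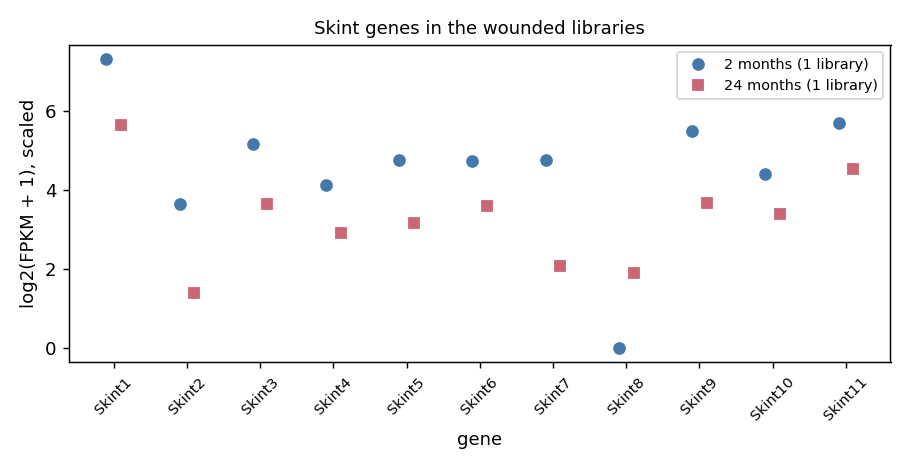
log2(FPKM + 1), after size factors, of each Skint gene in the wounded library at 2 months (circles) and at 24 months (squares). Skint1 is at 158 and 49.5 FPKM, all 10 genes above the filter are lower at 24 months, and Skint8, below the filter, is listed at 0 at 2 months.

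Inflammatory cytokines had a median of -0.83 (percentile 0, 13 of 18 lower), with Il6 at 7.11 and 1.42 FPKM and Ccl27a, a keratinocyte chemokine that attracts T cells, at 1645 and 213 FPKM. Interferon response genes had -0.53 (percentile 0.28). Medians were positive for hemidesmosome and basement membrane (1.29), Notch (1.24), Wnt (1.10), bulge markers (1.07), antimicrobial defence (0.84), cholesterol synthesis (0.80), immediate early (0.72), JAK-STAT (0.70), wound response (0.66) and cell cycle genes (0.43, 30 of 35 higher), all at percentiles from 98.6 to 100. Against random lists matched on length as well, JAK-STAT (0.60) lay at percentile 96.4, inside that central range of -0.22 to 0.67, and the other 9 at 97.7 to 100. The filter kept 13 of 18 hemidesmosome, 6 of 14 Notch, 5 of 20 Wnt and 10 of 25 bulge marker genes. Some passed only through the aged library, as Sox9 (2.43 and 6.98 FPKM), Nfatc1 (2.63 and 6.50) and Notch3 (2.13 and 6.65). How many passed through 1 library only, either way, was not counted. Cd34 was at 0.839 and 0.930 FPKM, so the bulge list does not show bulge cells here. Stat3, a transducer of cytokine signals, was at 26.9 and 74.9 FPKM, Mki67 at 16.8 and 35.0, and the differentiation keratin Krt10 at 1280 and 1233. Ribosomal proteins were lower for 48 of 48 (-1.11, percentile 0.435), MHC class I genes had a median of -0.16 and a mean of 0.18, and epidermal differentiation genes -0.05.

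Of 9388 genes, 1356 were at least 2-fold higher and 824 at least 2-fold lower in the aged wounded library, and 1591 and 519 in FPKM as deposited. These counts include genes among the 266 that were listed at 0 in 1 library. Of the genes above 0 in both, counted after the data were seen, 1218 were higher and 696 lower. The 24 largest ratios all had one library listed at 0, so no fold is given for them. Among genes of at least 1 FPKM in both libraries, a selection made after their values were seen, the highest were Fat1 (2.69), Tnks1bp1 (2.66), the non-muscle myosin Myh9 (2.64), Ppard (2.47), Sipa1l3 (2.45), Atp11a (2.41), Notch1 (2.36) and the glycolytic enzyme Eno1 (2.34, 107 and 547 FPKM). The lowest were the gut hormone Pyy (-3.78), Ccl27a (-2.95), the metallothionein Mt4 (-2.78), Skint7 (-2.68) and Mill1 (-2.62). Across 9122 genes the ratio rose with transcript length (Spearman 0.46, genes not being independent replicates), with medians from -0.47 in the shortest of 4 length classes to 0.43 in the longest. Both wounded libraries held Xist, at 45.4 and 35.3 FPKM, and Eif2s3y was listed at 0 at 2 months and at 0.0573 FPKM at 24 months.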

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

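All tests weighed in this part, with their bounds, were chosen only after the result they address was seen, and several bounds were then made stricter, among them that for antigen-presenting cells, which 4 pairs would first have argued against; the difference tests between ages and populations were planned.

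By the planned camera test of the difference itself, activation differed between 2 and 24 months for 3 lists, immediate early and stress genes by a median of -1.01, cholesterol synthesis genes by -0.42 and interferon response genes by 0.29, and each had adjusted p = 0.969 with an estimated correlation. Each depends on single libraries, such as these: without replicate 2 of activated cells at 24 months the immediate early difference was -0.19 and that of cholesterol synthesis 0.03, and without replicate 1 that of interferon response 0.08. The age difference differed between telogen bulge and epidermis for bulge stem cell markers by 0.31 and for cell cycle genes by -0.33, each with adjusted p = 0.994 with an estimated correlation; the cell cycle value was 0.04 without replicate 2 of epidermis at 2 months, and the bulge marker call was lost when any 1 of 3 libraries was left out. In the wounded libraries, 67 spliced assembled transcripts outside annotated genes stood at 5 FPKM or more at 2 months and 72 at 24 months, data that the comparisons did not use.

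MHC class I presentation genes lay higher at 24 months in each of the 3 sorted populations by camera, but with adjusted p = 0.981, 0.939 and 0.791 with an estimated correlation in telogen bulge, epidermis and activated cells, and the epidermis median was -0.20 without replicate 2 at 2 months. The authors' normalization as the whole cause is argued against by the median of 0.36 after median-ratio scaling. T cells in the aged sorts stay open as a candidate explanation. The mean of the T cell list was higher in 6 of 6 same-number pairs, though by as little as 0.02 in a pair. In the telogen bulge Cd3g went from 1.09 to 2.07 FPKM and Cd247 from 2.87 to 2.96 while B2m went from 908 to 1254. Ptprc, Cd2 and Itgae went there from 0.108, 0.170 and 0.120 to 0.103, 0.156 and 0.0702 FPKM. Cd3d rose there from 0.106 to 0.245 FPKM and Il2rb from 0.149 to 0.235, so these trace genes did not move one way. In epidermis Ptprc, Cd2 and Itgae went from 0.110, 0.0781 and 0.0976 to 0.348, 0.390 and 0.240 FPKM. In activated cells they went from 0.418, 0.291 and 0.339 to 0.461, 0.348 and 0.322. These values are too near 0 to decide. Of the list's genes, 8 passed the expression filter, and the labels do not state the sort's gates. Antigen-presenting cells stay open, with the MHC class II and Langerhans cell list higher in 4 of 6 pairs, and so does a batch that the labels do not give, while a batch by replicate number is balanced over the ages, so that the count of pairs with a higher MHC class I mean (6 of 6, and 5 when the numbers of one population were crossed) decides nothing about it. Age itself stays open: the exact two-sided p over 64 exchanges of age within pairs can be no smaller than the 0.03125 seen for 4 lists (chance gives 0.969), which is 0.242 after adjustment over 31 lists, and since a list at that value passes only if most of the 31 lists reach it too, the test decides nothing for this one.

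Skint genes lay lower in the aged wounded library. A transcript length difference between the 2 libraries is argued against by percentile 0 among random lists matched on length and expression, and reads shared between the near-identical copies by a log2 ratio of -1.59 for the family's summed FPKM. Fewer differentiated cells are argued against by a median of 0.024 (SD 0.643) over 16 epidermal differentiation genes. The spread between libraries of one group stays open, since the family's mean differed by 1.61 between the wounded libraries and, between the 2 libraries of a group, by 1.73 in activated cells, 1.04 in telogen bulge and 0.52 in epidermis at 2 months, but by 0.24, 0.16 and 0.05 at 24 months. Age stays an open and untested explanation, with 1 library per age.

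In epidermis and activated bulge stem cells, replicate 2 differed from replicate 1 at both ages. A difference in depth is argued against, since the rank correlation of the difference with transcript length was 0.60 in the group with the smallest depth difference (ratio 1.06). Gene length bias, as RNA quality could give, stays open, with rank correlations from 0.24 to 0.60 in the 4 groups, though -0.32 and 0.13 in telogen bulge at 2 and 24 months, and Malat1, a long nuclear RNA, 2.38 to 4.23 higher on the log2 scale in replicate 2. Differentiated cells in the replicate 1 libraries stay open beside it. After the length trend was removed, differentiation genes still lay below random sets in 3 of 4 groups, a part that the length trend does not account for. Their medians were then -2.60 and -1.11 in activated cells at 2 and 24 months. In epidermis they were -0.17, inside the random range, and -0.42. In telogen bulge at 2 months the median was 1.63, the other way. The design has no group for this pattern, so no biological explanation was tested, apart from that mix of cells.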

How the results depend on the processing

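The tests chosen only after the data were seen are the block within each population and the crossed block, library weights, equal library totals, leaving out replicate number 1 or 2 of both epidermis and activated cells, each library left out for the lists, and the annotated transcripts alone; the others were planned. The median SD within a group was 0.110 and 0.0642 in telogen bulge but 0.297 to 0.383 in epidermis and activated cells, with 2 libraries per group. Of single named gene values, 36876 stayed alike, 1483 moved, 1011 became stronger, 530 weaker and 0 reversed. Of list values, 5391 stayed alike, 38 moved, 336 became stronger, 326 weaker and 29 reversed. Alike means still called in the same direction, or still uncalled, for genes within the standard error of the main value. Reversal was counted only for values called in the main fit. A change of sign among values that stayed uncalled, as all genes in the main age tests were, was thus not counted. For each count of genes 27 settings were run, 21 planned, and age gave at least 1 gene in 7 for telogen bulge, 5 for epidermis, 3 for activated cells and 5 for the mean. The settings run include leaving out replicate number 1 or 2 of both epidermis and activated cells, where only telogen bulge gave the spread. The wounded count of 2180 genes stayed within 1.5 times under all 4 alternatives, from 2110 to 2786. Except where said, the cause of a move was not tested.

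Without a filter on low values, age gave 10 genes in telogen bulge, 4 in epidermis, 10 in activated cells, 5 for the mean and 6 for the difference between bulge and epidermis. Quantile normalization gave 2682 and 1751 genes for activation at 2 and 24 months. Only the groups compared gave 1 gene for age in telogen bulge and 948 and 2304 for activation. Library weights, which favour the telogen bulge libraries, gave 222 for age in telogen bulge and 2876 for activation at 24 months. Without number 2 of epidermis and activated cells, age gave 1, 29 and 29 genes and the mean 105, activation 5866 and 5599, its difference 10, and bulge against epidermis 6442; without number 1, 1 and 526 for telogen bulge and epidermis, 7923 and 7658 for activation and 8055 for bulge against epidermis. Of 74 list calls, 2 held with an estimated correlation, and fry called 16, of which 11 are among the 74.

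The labels give groups the same replicate numbers, and same-number deviations between ages correlated at -0.125 in telogen bulge, 0.507 in epidermis and 0.787 in activated cells. Since telogen bulge lacked such a link, the numbers were not taken to pair the samples in the main fit. The deviation shared in epidermis and activated cells thus stays in the spread of the main tests and widens it. The counts over same-number pairs and the exact tests do rest on these numbers, also in telogen bulge. The replicate block by number gave 2416 and 1693 genes for activation and changed no other count by more than 1.5 times. The replicate block within each population gave 2 for age in epidermis, 24 for the mean, 5514 and 5288 for activation and 5335 for bulge against epidermis. The block with crossed numbers gave 1610 for activation at 24 months.

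Leaving out 1 library gave 0 to 1 genes for age in telogen bulge, 0 to 1 in epidermis, 0 to 6 in activated cells, 0 to 2 for the mean and 0 to 1 for the difference of activation. It gave 412 to 1953 and 278 to 1266 for activation, 1289 to 2675 for bulge against epidermis and 61 to 104 list calls. List medians for age ran as follows. In telogen bulge, epidermal differentiation ran from -0.29 to 1.17. In epidermis, MHC class I ran from -0.20 to 0.81, ribosomal from -0.16 to 0.97, oxidative phosphorylation from -0.30 to 0.79 and Wnt from -0.36 to 0.0092; immediate early ran from 0.24 to 0.43, so only the direction of its test turned. In activated cells, Hedgehog ran from -0.82 to 0.22, bulge markers from -0.060 to 0.31, ribosomal from -0.32 to 0.56, fibroblast from -2.17 to 0.21, wound response from -1.20 to 0.57 and macrophage from -1.42 to 0.58. For the mean, Hedgehog ran from -0.31 to 0.092, differentiation from -0.13 to 0.74 and oxidative phosphorylation from -0.093 to 0.28. Without number 2, medians were 0.0033 for Wnt, -0.18 for oxidative phosphorylation and -0.057 for ribosomal in epidermis, 0.21 for Hedgehog in activated cells, and 0.017 for differentiation, 0.089 for Hedgehog and -0.059 for oxidative phosphorylation in the mean; without number 1, -0.25 for bulge markers, 0.19 for wound response and 0.086 for macrophage in activated cells, and -0.26 for immediate early genes in activation at 24 months.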

Other observations

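The comparison of wounded with resting epidermis, the exact test of the sebaceous list and the count over other splits were chosen only after the data were seen.

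Each wounded library was also set beside the resting epidermis of its age, without a test, over 8457 genes and across 2 annotations, and the wounded libraries held Xist where the resting ones held Y-linked RNA. Antimicrobial defence genes had median log2 differences of 2.91 at 2 months and 2.69 at 24 months, and keratinocyte wound response genes of 1.70 and 1.48. Skint genes had 2.39 and 0.82, cytokines 1.5 and 0.51, and ribosomal proteins 1.21 and -0.40. Il6 went from 1.45 to 8.53 FPKM at 2 months, and from 2.20 to 1.53 at 24 months, on a scale of size factors taken over resting and wounded libraries together, where the wounded pair alone gave 7.11 and 1.42.

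Markers of other cells varied between libraries of one group. The collagen-binding proteoglycan Dcn, made by fibroblasts, was at 112.8 FPKM in replicate 1 and 0.3 in replicate 2 of activated bulge stem cells at 2 months, and Elovl3, of sebocytes, at 54.2 and 3.1. Dct, an enzyme of melanocytes, was at 20.7 and 5.1 FPKM in the 2 telogen bulge libraries at 2 months and at 4.3 and 3.2 at 24 months. The mean log2(FPKM + 1) of the 4 melanocyte genes above the filter was lower at 24 months in 6 of 6 same-number pairs, with 3.61 and 2.33 at 2 months and 1.97 and 1.90 at 24 months in telogen bulge, a list too small to be tested.

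Sebaceous gland genes lay lower at 24 months in all 6 same-number pairs. Age stays open, since the exact two-sided p over 64 exchanges of age within pairs, 0.242 after adjustment over 31 lists, comes from the smallest unadjusted value that 64 exchanges can give, at which a list passes only if most of the 31 reach it too, so the test decides nothing for this list.

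For the mean age difference limma called 0 genes, with 281 at an unadjusted p under 0.05. Of 100 splits drawn from the 108 possible splits of the 12 libraries within populations, 100 gave at least 0 genes, as any split must, so that count decides nothing. By genes at an unadjusted p under 0.05, 57 of the 100 splits, the real one among them, gave at least 281, so chance cannot be excluded. Other splits called genes in 46 cases, and the highest gave 6523, which points to a structure of the samples other than age. The 4 splits parting the replicate numbers in all 3 populations gave 7, 18, 4890 and 5754 genes; whether the numbers in epidermis and activated cells alone make up that structure was not tested.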
